A study of Danio rerio with 12 samples.

How the data were processed

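Whole zebrafish embryos were sampled in 4 groups of 3 biological replicates (control, SiNPs, BaP and SiNPs_BaP), each measured on 1 ZebGene Affymetrix array. Per the labels' protocols, embryos were treated from 2 dpf for 24 h by injection of 10 nL, total RNA was extracted with Trizol at 3 dpf, and biotin-labelled material was hybridised. The labels give the strain as "Ablino embryos" and the tissue as whole embryos. The deposited values are on the log2 scale: the authors summarised and normalised the arrays to gene level with RMA, which corrects the background, sets all arrays to a common distribution and summarises probes, per the submitters' processing notes. The software, its version and the library files were not given in the sources used here. Because of the common distribution, a shift of all transcripts at once would not appear in these values, and differences of weakly expressed genes are compressed toward 0. The values ran from 1.0065 to 12.7313, with array medians of 3.2972 to 3.3348, and all 12 value columns belonged to a sample.

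Of 75212 rows, 20856 carried 1 symbol in the platform annotation, 805 several and 53551 none. Rows with several symbols or none were tested but not assigned to a gene. Of the rows with 1 symbol, 20323 matched an NCBI gene table (assembly GRCz12tu, used for names alone), which updated 1 symbol. They stood for 19298 genes, 1377 of them with more than 1 row, where the row of highest mean over all arrays was taken. Of the genes, 2326 had placeholder symbols. A total of 14289 rows shared all 12 values with another row.

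Groups were compared with limma 3.58.1 in R 4.3.3 on the deposited values, with no filter on low values. All 12 arrays entered 1 linear model with a coefficient per group and empirical Bayes variances (8 residual degrees of freedom, prior 2.92). The 6 contrasts were each treatment against control, the joint treatment against each single treatment, and the interaction; an F test asked for any difference among the groups. Tests were two-sided, with Benjamini-Hochberg adjustment over the 75212 rows and a threshold of 0.05. Errors given with log2 differences are standard errors from the model. The model was tested on simulated data with 200 of 75212 rows changed, by log2 differences of 0.5, 1 and 2. It recovered 25.4%, 67.2% and 93.9% of them for SiNPs against control, 19.4%, 76.1% and 93.9% for BaP, and 26.9%, 70.1% and 95.5% for the joint treatment. It also called 3, 7 and 8 unchanged rows in these contrasts. The simulated noise was independent between rows, with 1 SD per row in all groups, so recovery in the real data may differ.

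A total of 31 gene lists with 967 entries was fixed, of which 30 had measured members and were tested: AHR targets, other xenobiotic metabolism, Nrf2 and oxidative stress, inflammatory signalling, neutrophil and macrophage markers, interferon, complement and acute phase, coagulation, endothelium, cardiac muscle, skeletal muscle, erythroid and globin, liver and yolk plasma proteins, pancreatic enzymes, intestine, photoreceptor, lens, neurons, glia, cell cycle, p53, heat shock and unfolded protein response, cholesterol and fatty acid synthesis, hypoxia, circadian clock, glucocorticoid response, lysosome, extracellular matrix, epidermis and pigment cells. The remaining list, mitochondrially encoded genes, had 0 measured members. Some lists share genes. For example, igfbp1a stands in the hypoxia and the glucocorticoid list, and vegfaa in the endothelial and the hypoxia list. The genes mmp9, mmp13a and timp2b stand among the neutrophil and macrophage markers alone. Each list was tested with camera at a preset correlation of 0.01, with adjusted p over the 30 lists of a contrast, and again with a correlation estimated from the residuals. Such a test compares the list with the other genes. The calls that held with an estimated correlation were inflammatory signalling and erythroid genes for SiNPs, erythroid genes and hypoxia targets for BaP, and inflammatory, photoreceptor, hypoxia, p53, erythroid, neutrophil and macrophage, and interferon lists for the joint treatment. The limma test fry, which asks whether a list's genes moved one way on balance, was run as well.

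Genes were named by a rule. Against control, it took up to 8 genes each way with the largest log2 difference among those past the threshold whose 3 treated arrays all lay on 1 side of the 3 controls, and elsewhere 5 each way. Where fewer than 5 passed, genes of smallest p filled up to 5 and are said not to pass. Up to 4 members of each list past the threshold and 2 of other lists could be named, as could cyp1a, cyp1b1, cyp1c1, ahrra, hmox1a, il1b, mmp9, mpx, nppa and f2 throughout; no row carried cyp1a or cyp1c1 alone. Placeholder symbols were counted and not named, apart from 2 in a count of 5. The groups, tests, lists, naming rule and other settings to be tried were set before the data were examined.

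The other settings were a variance prior with trend and robust estimation, leaving out the lowest 25% of rows by mean, 1 row per named gene, median centring, cyclic loess, array weights, the replicate number as a block, the arrays of the compared groups alone, the mean of a gene's rows, a fold of at least 1.5, an estimated correlation for the lists, and leaving out each array in turn. Counting identical rows once was added after seeing the data, and so was adjusting the p of the fit of all rows over 1 row per named gene. Correlations between comparisons that share arrays were set against 20 simulated draws of unchanged groups. Overlaps of called genes were set against the same draws, after seeing the data. Calls were also counted for the 10 splits of each pair of groups and for 100 regroupings of all arrays. Tables were handled with Python 3.11.15 and pandas 2.3.3, and plots drawn with matplotlib 3.10.9.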

Results

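Gene expression was measured in whole zebrafish embryos with 12 Affymetrix gene arrays, 1 per sample. The embryos formed 4 groups of 3 biological replicates each. They were controls, embryos treated with silica nanoparticles (SiNPs) and embryos treated with the polycyclic aromatic hydrocarbon benzo[a]pyrene (BaP). The fourth group received both and is called the joint treatment (SiNPs_BaP). Treatment began at 2 dpf and lasted 24 h, and RNA was taken at 3 dpf. Per the labels' protocols, anaesthetised embryos received 10 nL by microinjection into the Duct of Cuvier, a large vein over the yolk. The doses, the vehicle and whether the controls were injected were not given in the sources used here. Each array gave 75212 rows of log2 expression values, of which 20856 carried 1 gene symbol. Of these, 20323 matched a gene table and stood for 19298 genes. Arrays of a group correlated at r = 0.9857 to 0.9904 over all rows (12 pairs), and arrays of different groups at 0.9826 to 0.9901 (54 pairs). The number of arrays limits the precision of all values given here.

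On the first principal component of the 12 arrays, with 17.8% of the variance, controls lay at -32.4 to -26.4, SiNPs at -6.2 to -3.7, BaP at -7.3 to 0.6 and the joint treatment at 28.1 to 47.6. The ranges of the single treatments overlapped there, and on the second component all 4 groups overlapped. The third component, with 9.83%, set SiNPs array 1 (-40.5) and SiNPs_BaP array 1 (-34.1) apart from the others. A test of any difference among the 4 groups passed an adjusted p of 0.05 in 1220 rows.

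**Figure D1:**
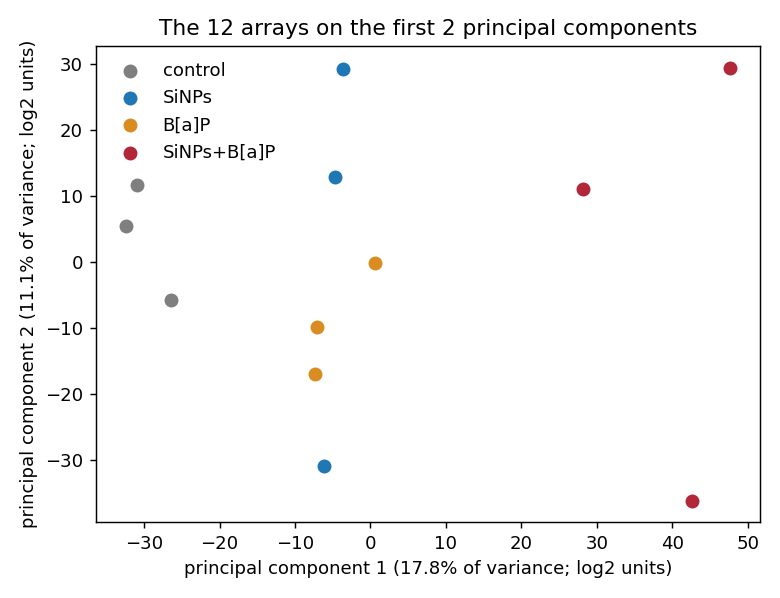
Each point is 1 array, placed by its scores on the first (17.8% of the variance) and second (11.1%) principal components of the log2 values. The 3 control arrays lie at -32.4 to -26.4 on the first component and the 3 arrays of the joint treatment at 28.1 to 47.6, with both single treatments between them.

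The comparison of SiNPs-treated embryos with controls addressed the response to the particles alone. Genes of cytokine signalling rose. The log2 difference ± SE, with n = 3 arrays per group here and throughout, was 1.55 ± 0.21 for socs3b, a feedback inhibitor of cytokine receptors (adjusted p = 0.0299). It was 1.05 ± 0.12 for il6st, the receptor subunit shared by interleukin 6 family cytokines (0.0164). The chemokine genes rose too, ccl34a.4 by 1.39 ± 0.10 (9.73e-04) and cxcl18b by 1.28 ± 0.14 (0.0139). Also higher were fgfr1bl, a gene named after a fibroblast growth factor receptor, by 1.61 ± 0.12 (0.00108), and clu, a secreted chaperone, by 1.17 ± 0.13 (0.0150). Further genes that rose were c7a, a component of the complement attack complex, by 1.06 ± 0.13 (0.0215), and fn1b, a fibronectin, by 1.00 ± 0.14 (0.0308). Genes of red blood cells were lower. The log2 difference was -1.29 ± 0.11 for alas2, which makes the first enzyme of heme synthesis (0.00280), -0.998 ± 0.114 for the embryonic globin hbbe2 (0.0164) and -0.78 ± 0.08 for the globin hbae3 (0.0106). The photoreceptor calcium sensor rcvrn3 fell by 0.84 (SE 0.11, 0.0306) and lrrc4.2, a synaptic adhesion gene, fell by 0.60 (SE 0.07, 0.0164).

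In all, 43 rows passed in SiNPs against control, 26 higher and 17 lower, and 21 of them carried no symbol. They stood for 15 genes that rose and 7 that fell, 2 of the 7 with placeholder symbols. At an unadjusted p under 0.05 there were 6185 rows, and 18.7% of genes had their 3 treated arrays apart from the 3 controls, against 10% by chance. The count was 4 without control array 2, 5 without control array 3, 17 without SiNPs array 1, 10 without SiNPs array 2 and 5 without SiNPs array 3. Of the 13 genes named above, fgfr1bl, ccl34a.4 and alas2 passed without each of the 6 arrays in turn, whereas the other 10 lost their call without control array 2 (adjusted p = 0.0820 to 0.111) and without SiNPs array 3 (0.0736 to 0.162).

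By gene list, inflammatory signalling rose with SiNPs. The median of its 37 measured members was 0.36 (adjusted p = 3.30e-21; 0.0234 with an estimated correlation), with array medians of 0.33 to 0.48 above the control mean. Over all rows 3 members rose, the transcription factor stat3 (0.79 ± 0.09, 0.0139), socs3b and the NF-kB inhibitor nfkbiaa (0.54 ± 0.08, 0.0398). Adjusted over the list alone 22 rose and 0 fell. The interleukin il1b (1.67 ± 0.50, adjusted p = 0.40) did not pass, nor did the metalloproteinase mmp9 of the neutrophil and macrophage list (1.35 ± 0.40, 0.399). The erythroid and globin list fell, with a median of -0.31 over 21 members (8.92e-11; 0.0210 with an estimated correlation), where 3 members fell over all rows and 11 adjusted over the list alone. Photoreceptor genes also fell, with a median of -0.40 over 39 members (1.75e-16; adjusted p = 0.0954 with an estimated correlation). In that list 1 member was lower over all rows, and 21 were lower and 1 higher adjusted over the list alone. Neuron and synapse genes had a median of -0.15 (37 members, 5 lower adjusted over the list alone; 5.85e-08, and 0.0954 with an estimated correlation).

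Shifts passed in 9 other lists with SiNPs, and each lost its call with an estimated correlation. Complement and acute phase genes rose by a median of 0.16 (6 of 17 adjusted over the list alone; adjusted p = 1.76e-06, and 0.189 with an estimated correlation), and neutrophil and macrophage markers by 0.15 (2 of 24; 0.00118 and 0.0954). With the values in the same order, endothelial markers rose by 0.088 (1 of 35; 0.00118 and 0.198), lysosome and endosome genes by 0.086 (6 of 31; 2.97e-04 and 0.198) and epidermis and ionocyte genes by 0.082 (6 of 31; 4.23e-05 and 0.198). Adjusted over the list alone, 0 members passed in limma in the p53 and DNA damage list (median 0.085; 0.00162 and 0.117) and the heat shock and unfolded protein list (0.060; 0.00702 and 0.257). The same held for the pancreatic enzyme list (-0.13; 0.00702 and 0.198) and the cell cycle list (0.057; 0.0353 and 0.292). The cell cycle call ended without control array 2 (0.0937), control array 3 (0.0559) or SiNPs array 1 (0.140), and the pancreatic call without control array 1 (0.0511) or SiNPs array 1 (0.0510). Members that rose over all rows in these and other lists, beside c7a and fn1b given above, included irf9, a transcription factor of interferon signalling (0.99 ± 0.11), and the endothelial scavenger receptor stab2 (0.61 ± 0.08). They also included igfbp1a, which binds insulin-like growth factors and sits in both the hypoxia and the glucocorticoid list (0.94 ± 0.12), and the autophagy adaptor sqstm1 (0.67 ± 0.10). With 1 of the 6 arrays left out, irf9 kept its call only without control array 1 and igfbp1a only without SiNPs array 1, while stab2, sqstm1, nfkbiaa and socs3b lost theirs each time (adjusted p = 0.0671 to 0.186 where lost). The call of stat3 was lost without control array 2 (0.0820), control array 3 (0.0671), SiNPs array 2 (0.0584) or SiNPs array 3 (0.0827). The hypoxia list did not pass, with a median of -0.001 and a mean of 0.096 (0.0602). The aryl hydrocarbon receptor (AHR) target list had a median of -0.001 (0.425) and the Nrf2 list 0.018 (0.229).

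The comparison of BaP-treated embryos with controls addressed the response to benzo[a]pyrene alone. The largest difference was in a row that lists 2 symbols, cyp1a, which encodes the cytochrome P450 classically induced through the AHR, and mpx, the neutrophil myeloperoxidase. This row, singled out after its values were seen, was 3.51 ± 0.15 higher on the log2 scale, or 11.4-fold (95% interval 3.18 to 3.85 on the log2 scale, adjusted p = 1.00e-05). Its group means were 4.36 ± 0.17 (SD, n = 3) in controls, 4.53 ± 0.09 with SiNPs, 7.87 ± 0.29 with BaP and 7.95 ± 0.20 with the joint treatment. The row of mpx alone did not pass with BaP (0.14, adjusted p = 0.854), and no row carried cyp1a alone. Named genes that fell were epd, an ependymin glycoprotein (-1.20 ± 0.13, 0.0319), the trypsin gene prss59.2 (-1.19 ± 0.15, 0.0449) and rcvrn3 (-0.92 ± 0.11, 0.0449). The placeholder genes si:ch211-76l23.4 (-0.79) and LOC559131 (-0.76) fell too; both were named after their values were seen because the count was so small.

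With BaP, 14 rows passed, 6 higher and 8 lower, against 5728 at an unadjusted p under 0.05. Among genes with a row of their own, 0 rose and 5 fell in limma. The groups lay apart in 18.1% of genes, against 10% by chance. The count fell to 2 without control array 2 and to 1 without control array 1, control array 3, BaP array 1, BaP array 2 or BaP array 3, and the row of cyp1a and mpx passed in each of these fits. Neither epd nor rcvrn3 kept its call without any of the 6 arrays (adjusted p = 0.0604 to 0.211), and prss59.2 kept it without control array 2 alone (0.130 to 0.223 without the others). The genes of smallest p among those higher, which did not pass, were the glutathione transferase gstp1.2 (0.57 ± 0.09), stab2 (0.55), clu (0.85) and mfap4.2 (0.61), with an adjusted p of 0.10 each. Among those lower, not passing either, were the photoreceptor disc gene rom1a (-0.96) and the urate oxidase gene uox (-1.02), with 0.0866 each.

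By gene list, photoreceptor genes fell with BaP, with a median of -0.45 over 39 members (adjusted p = 1.10e-23, and 0.0613 with an estimated correlation) and array medians of -0.57 to -0.33. Over all rows 1 member was lower, and 26 were adjusted over the list alone. Erythroid and globin genes fell, with a median of -0.25 over 21 members and 10 lower adjusted over the list alone (8.37e-07, and 0.0456 with an estimated correlation). Hypoxia targets rose by 0.11 over 27 members, with 9 higher and 1 lower adjusted over the list alone (1.28e-05, and 0.0345 with an estimated correlation). The member egln3, an oxygen-sensing hydroxylase (0.82, 0.129), did not pass over all rows. Inflammatory signalling rose by a median of 0.21 with 0 members past the test adjusted over the list alone (1.73e-09; adjusted p = 0.0906 with an estimated correlation). In that list il1b stood at 1.06 ± 0.50 (0.674), and mmp9, from the neutrophil and macrophage list, at 0.79 ± 0.40 (0.704).

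Genes of digestive organs and lipid synthesis were lower with BaP as lists, without a call under an estimated correlation. The liver and yolk plasma protein list had a median of -0.27 (7 of 28 lower adjusted over the list alone; adjusted p = 2.83e-06, and 0.254 with an estimated correlation), and pancreatic enzymes -0.20 (8 of 23; 4.27e-06 and 0.0840). Intestine genes had a median of -0.19 (2 of 17 lower and 1 higher; 0.00426 and 0.30) and cholesterol and fatty acid synthesis genes -0.13 (5 of 28; 1.47e-05 and 0.154). Neuron genes shifted by -0.11 (1.07e-04 and 0.162), endothelial markers by 0.060 (1.07e-04 and 0.154), and p53 genes by 0.087 (0.0119 and 0.154). The shift was 0.11 for neutrophil and macrophage markers (0.0179 and 0.154), 0.083 for lens genes (0.0207 and 0.606) and -0.076 for cell cycle genes (0.0219 and 0.270). The AHR target list, of which 13 members had a row of their own, had a median of 0.054 and did not pass (0.0530), though it passed with fry (adjusted p = 0.037). The intestine call ended without control array 1 (0.0722) or control array 3 (0.0525), the cell cycle call without control array 1 (0.0722) or BaP array 2 (0.0986). The neutrophil and macrophage call ended without control array 2 (0.0859) or BaP array 1 (0.108), and the p53 call without control array 3 (0.0553) or BaP array 1 (0.0788). The lens call ended without control array 2 (0.0615), control array 3 (0.436), BaP array 2 (0.0722) or BaP array 3 (0.174).

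The comparison of the joint treatment with controls addressed the response to both agents given together. The genes with the largest rise were cbx7a, a Polycomb chromatin component (4.24 ± 0.39, adjusted p = 2.40e-04), fosl1a, a subunit of the transcription factor AP-1 (4.09 ± 0.44, 6.26e-04), the metalloproteinase inhibitor timp2b (3.96 ± 0.30, 9.20e-05) and il1b (3.79 ± 0.50, 0.00225). Next came the matrix metalloproteinases mmp9 (3.44 ± 0.40, 0.00108) and mmp13a (2.88 ± 0.39, 0.00279), the leptin gene lepb (2.88 ± 0.29, 4.28e-04) and tinagl1, a secreted matrix-associated protein (2.62 ± 0.18, 8.93e-05). The mean level of il1b was 3.99 ± 0.10 (SD, n = 3) in controls, 5.66 ± 1.2 with SiNPs, 5.05 ± 0.66 with BaP and 7.77 ± 0.39 with the joint treatment. Several of the largest falls were in genes of photoreceptors. They were rgs9a, which shuts off the phototransduction G protein (-1.93 ± 0.14, 9.20e-05), the disc rim gene prph2b (-1.73 ± 0.15, 1.93e-04), rcvrn3 (-1.73 ± 0.11, 8.30e-05) and the rhodopsin kinase grk1b (-1.71 ± 0.21, 0.00128). Also lower were leap2, a liver antimicrobial peptide (-1.93 ± 0.27, 0.00299), epd (-1.79 ± 0.13, 9.20e-05), the cytochrome P450 gene cyp2aa8 (-1.77 ± 0.34, 0.0160) and the trypsin gene prss59.1 (-1.70 ± 0.34, 0.0204).

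**Figure D2:**
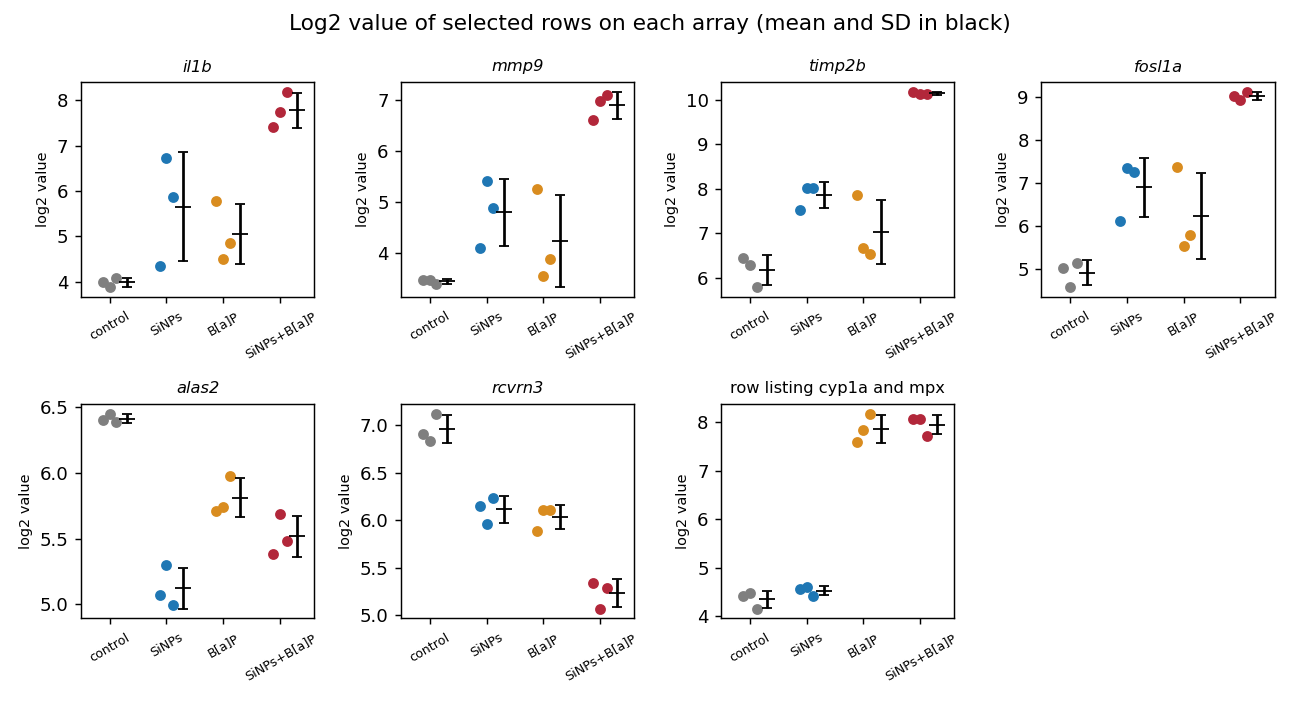
Log2 expression per array (points), with group means and SD (n = 3 per group), of il1b, mmp9, timp2b, fosl1a, alas2, rcvrn3 and the row listing cyp1a and mpx. The mean of il1b was 3.99 in controls and 7.77 with the joint treatment, whereas the row of cyp1a and mpx stood at 7.87 with BaP and 7.95 with the joint treatment, against 4.36 in controls.

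In the joint treatment 2744 rows passed, 1408 higher and 1336 lower, among them 642 genes with a symbol that rose and 793 that fell, 141 of these genes with a placeholder. An unadjusted p under 0.05 was reached by 12023 rows. The 3 treated arrays lay apart from the controls in 32.4% of genes, against 10% by chance, and 196 of the called genes differed by more than 1 on the log2 scale. The count was 1561 without control array 3, 1598 without SiNPs_BaP array 2, 1622 without control array 1, 1724 without control array 2 and 1818 without SiNPs_BaP array 1. Of the 16 genes named above, 14 passed without each of the 6 arrays in turn, whereas cyp2aa8 lost its call without SiNPs_BaP array 1 (0.0530) or 3 (0.0574) and prss59.1 without SiNPs_BaP array 1 (0.0718) or 2 (0.0650).

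**Figure D3:**
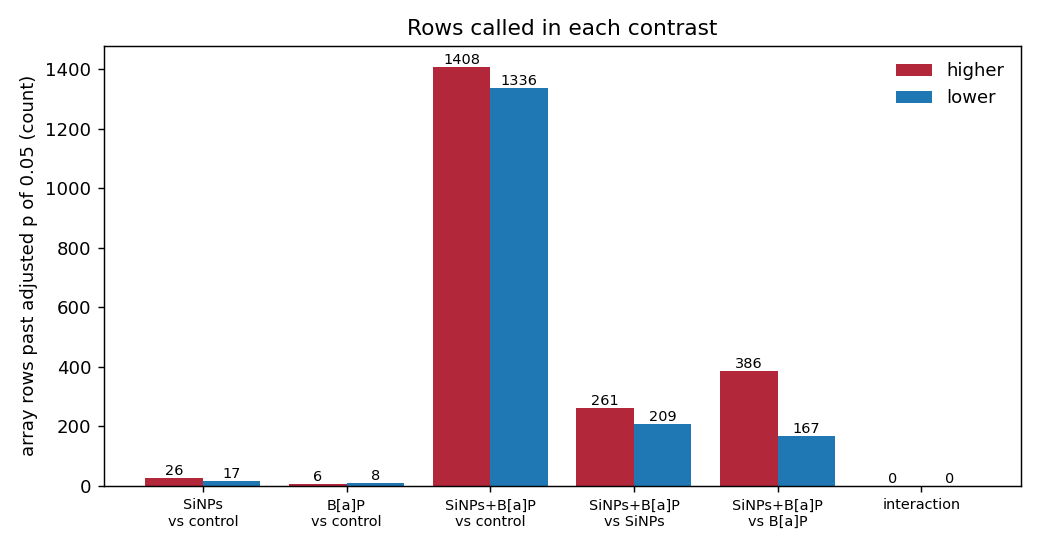
Number of rows with an adjusted p under 0.05 (vertical axis), higher and lower, in each comparison. The joint treatment had 1408 higher and 1336 lower rows against control, SiNPs 26 and 17, and BaP 6 and 8.

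Inflammatory signalling rose most among the lists in the joint treatment, with a median of 0.77 over 37 members (adjusted p = 1.12e-25; 0.0129 with an estimated correlation). Over all rows 25 members rose and 0 fell, and adjusted over the list alone 30 rose. They included stat3 (1.32 ± 0.09), socs3b (2.52 ± 0.21), jak1 (0.96), a kinase of cytokine receptors, and junbb (1.43), an AP-1 subunit. Neutrophil and macrophage markers rose by a median of 0.18 over 24 members (5.50e-04; 0.0493 with an estimated correlation). Of them 4 were higher and 2 lower over all rows, and 6 higher and 2 lower adjusted over the list alone. The members with the largest rise there, timp2b, mmp9 and mmp13a, encode a proteinase inhibitor and proteinases that other cells make as well. The carboxypeptidase gene cpa5 fell (-0.86), and mpx did not pass (0.13, 0.664). The interferon list rose by a median of 0.097 (3 of 21 over all rows and 5 adjusted over the list alone; 5.50e-04; 0.0324 with an estimated correlation), led by irf9 (1.21). Complement and acute phase genes did not pass, with a median of -0.092 but a mean of 0.10 (0.721), although c7a (1.39) and c4b (1.81), a complement component, rose. Coagulation genes did not pass either (median 0.044, 0.264), with 3 higher and 3 lower over all rows, among them f3b, a tissue factor gene (1.06, or 0.396 with an adjusted p of 0.0664 as the mean of its rows), and f2r, a thrombin receptor (0.97).

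Stress-response lists were higher in the joint treatment. Hypoxia targets rose by a median of 0.295 over 27 members (3.60e-07; 0.0129 with an estimated correlation). Of them 13 were higher and 1 lower over all rows, and 14 higher and 2 lower adjusted over the list alone. They included igfbp1a (1.69), egln3 (1.64), pfkfb3, a regulator of glycolysis (1.71), and the vasodilator peptide adma (1.56), while the glucose transporter slc2a1a fell (-1.37). The p53 and DNA damage list rose by 0.26 over 26 members (3.17e-06; 0.0324 with an estimated correlation). Over all rows 5 rose, and adjusted over the list alone 12 rose and 1 fell, with the cell death gene bbc3 (1.1) and btg2, an inhibitor of proliferation (0.97). Heat shock and unfolded protein response genes rose by 0.11 (7 of 35 over all rows and 8 adjusted over the list alone; 1.03e-04, and 0.102 with an estimated correlation). They included the chaperones dnajb1b (1.54) and hsp90aa1.2 (1.28) and the stress factors ddit3 (1.11) and trib3 (1.08). Lysosome and endosome genes rose by 0.13, 6 of 31 over all rows and 12 adjusted over the list alone (7.30e-06, and 0.102 with an estimated correlation), with sqstm1 (1.496) and the protease ctsba (0.74). The Nrf2 list passed narrowly (median 0.055, 0.0489; 0.356 with an estimated correlation) with 5 higher and 2 lower over all rows, and 8 higher and 3 lower adjusted over the list alone. In it prdx1 (1.14) and txnb (1.07), which reduce peroxides and disulfides, rose and the catalase gene cat fell (-0.62). Its call ended without control array 2 (0.143), control array 3 (0.0729), SiNPs_BaP array 1 (0.0728) or SiNPs_BaP array 2 (0.0621).

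Lists of differentiated tissues were mostly lower. Photoreceptor genes fell, with a median of -0.70 over 39 members (1.29e-19; 0.0493 with an estimated correlation). Over all rows 24 fell, and adjusted over the list alone 28 fell and 1 rose, including the ultraviolet opsin opn1sw1 (-1.38) and the cone transducin subunit gngt2b (-1.48). Erythroid and globin genes had a median of -0.33, 8 of 21 lower over all rows and 12 adjusted over the list alone (1.10e-05; 0.0376 with an estimated correlation). They included the transferrin receptor gene tfr1a (-0.83) and alas2 (-0.90). Neuron and synapse genes fell (-0.28, 9 of 37 over all rows and 22 adjusted over the list alone; 3.60e-07, and 0.0733 with an estimated correlation), among them syn1 (-0.55), a synaptic vesicle gene. Liver and yolk plasma protein genes fell (-0.41; 10 of 28 lower and 1 higher over all rows, 13 lower and 1 higher adjusted over the list alone; 1.40e-05, and 0.212 with an estimated correlation). They included uox (-1.41), the plasma fetuin gene fetub (-1.45) and hpda, an enzyme of tyrosine breakdown (-1.003). Extracellular matrix genes fell (-0.28; 11 of 35 lower and 2 higher, 19 lower and 5 higher adjusted over the list alone; 3.28e-04, and 0.198 with an estimated correlation). The small proteoglycans lum (-0.82) and dcn (-0.48) fell and fn1b (1.303) rose. Pancreatic enzymes had a median of -0.20 (5 of 23 lower over all rows, 9 lower and 1 higher adjusted over the list alone; 5.50e-04, and 0.102 with an estimated correlation). For intestine it was -0.26 (5 of 17 lower and 1 higher, 7 lower and 1 higher adjusted over the list alone; 6.56e-04, and 0.198 with an estimated correlation) and for pigment cells -0.20 (5 of 22 lower and 1 higher, 10 lower and 2 higher adjusted over the list alone; 0.00279, and 0.0936 with an estimated correlation).

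Proliferation and sterol genes were lower too. Cell cycle genes fell, with a median of -0.22 (4 of 31 over all rows and 15 adjusted over the list alone; 6.80e-05, and 0.0733 with an estimated correlation), with the ribonucleotide reductase gene rrm1 at -0.42. Cholesterol and fatty acid synthesis genes fell (-0.18; 6 of 28 over all rows and 10 adjusted over the list alone; 1.03e-04, and 0.111 with an estimated correlation), with hmgcs1 (-0.90) and hmgcra (-0.63) of sterol synthesis and the desaturase fads2 (-0.85). Endothelial markers rose (0.16; 7 of 35 higher and 1 lower, 10 higher and 1 lower adjusted over the list alone; 6.56e-04, and 0.141 with an estimated correlation), with stab2 (0.96) and the growth factor vegfaa (0.47). The hypoxia list holds vegfaa as well. Lens genes rose (0.16; 2 of 31 over all rows and 7 adjusted over the list alone; 0.00193, and 0.339 with an estimated correlation). The other 8 lists did not pass with camera, though AHR targets (adjusted p = 0.0161) and glucocorticoid response (0.0368) passed with fry. Over all rows 2 AHR targets rose and 2 fell, and 4 rose and 2 fell adjusted over the list alone. The medians and adjusted p of camera for the 8 lists were 0.13 and 0.125 for AHR targets, -0.13 and 0.0967 for other xenobiotic metabolism, 0.075 and 0.129 for glucocorticoid response, and -0.059 and 0.278 for the circadian clock. For tissues they were 0.057 and 0.107 for skeletal muscle, -0.092 and 0.721 for cardiac muscle, 0.006 and 0.746 for glia and myelin, and -0.056 and 0.953 for epidermis and ionocytes, the last 2 with means of -0.050 and 0.011, opposite in sign to the medians. Cardiac muscle had 0 of 30 members past the test in limma over all rows and adjusted over the list alone, with myl7, a heart myosin light chain, at -0.30 (0.160).

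**Figure D4:**
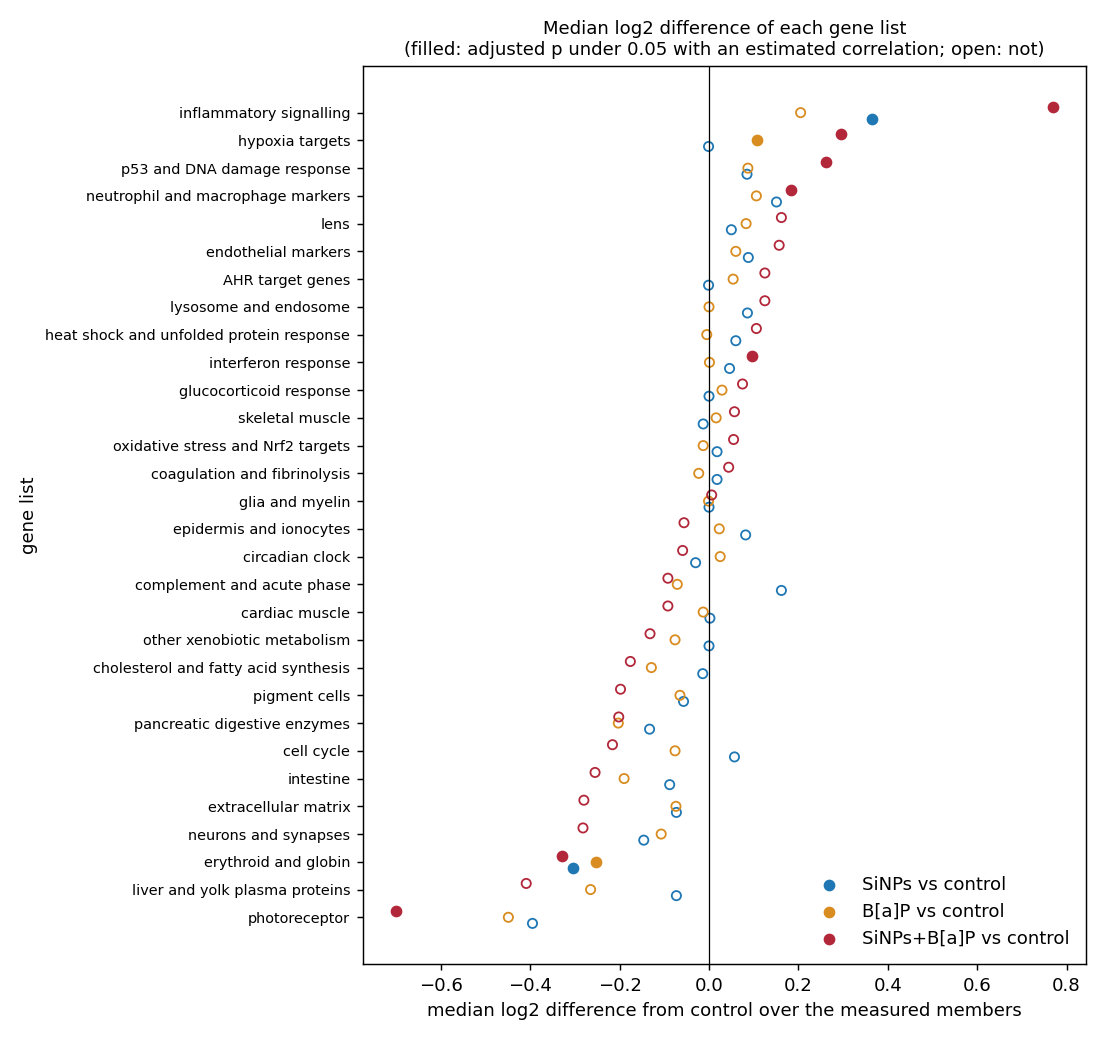
Median log2 difference from control (horizontal axis) of each of 30 gene lists with SiNPs, BaP and the joint treatment; filled points have an adjusted p under 0.05 with an estimated correlation. Inflammatory signalling stood at 0.36, 0.21 and 0.77 and photoreceptor genes at -0.40, -0.45 and -0.70.

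The comparison of the joint treatment with SiNPs addressed what BaP added to the particles. Higher with both agents were timp2b (2.28 ± 0.30, adjusted p = 0.0130), mmp13a (2.203 ± 0.394, 0.0377), mmp9 (2.09 ± 0.40, 0.0496), lepb (2.09 ± 0.29, 0.0152) and map1lc3cl, a gene of the autophagosome LC3 family (1.85 ± 0.35, 0.0453). Lower were rgs9a (-1.18 ± 0.14, 0.0108), the fast muscle troponin tnnc2.1 (-1.09 ± 0.13, 0.0108), uox (-1.03 ± 0.15, 0.0156), scpp5, a secreted phosphoprotein of mineralising tissue (-1.01 ± 0.12, 0.0108), and plac8.1 (-0.99 ± 0.16, 0.0239). The row of cyp1a and mpx was 3.42 higher (1.31e-05). In all, 470 rows passed, 261 higher and 209 lower, with 140 genes that rose and 128 that fell. At the unadjusted level 8325 rows had a p under 0.05, and 22.7% of genes lay apart, against 10% by chance.

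Against SiNPs, 20 lists passed, 8 higher and 12 lower, and 3 of them with an estimated correlation. Inflammatory signalling rose (median 0.43, 9 of 37 over all rows, 23 higher and 1 lower adjusted over the list alone; 2.10e-17; 0.0282 with an estimated correlation). So did hypoxia targets (0.27, 6 of 27 higher and 1 lower, 14 higher and 3 lower adjusted over the list alone; 1.25e-08; 0.00684 with an estimated correlation). Cell cycle genes fell, at -0.26 with 31 of 31 members lower in value, 2 past the test over all rows and 18 adjusted over the list alone (1.36e-11; 0.0226 with an estimated correlation). Photoreceptor genes fell (-0.43, 12 of 39 over all rows; 1.19e-14, and 0.0969 with an estimated correlation). The AHR target list rose (0.24, 1 of 13 over all rows, 6 higher and 1 lower adjusted over the list alone; 0.0118, and 0.0969 with an estimated correlation). The count of rows was 66 without SiNPs array 1, 74 without SiNPs_BaP array 2, 139 without SiNPs array 2, 147 without SiNPs_BaP array 1, 151 without SiNPs array 3 and 164 without SiNPs_BaP array 3. Of the 10 named genes rgs9a, tnnc2.1 and scpp5 passed without each array in turn. The calls of mmp9 and map1lc3cl were lost without any of the 6 (adjusted p = 0.0647 to 0.158), and those of timp2b, lepb, mmp13a, plac8.1 and uox without SiNPs array 1 (0.0629 to 0.103) or SiNPs_BaP array 2 (0.0560 to 0.123). Without SiNPs_BaP array 3 those of lepb (0.0518), uox (0.0509), mmp13a (0.116) and plac8.1 (0.0838) were lost as well. Without SiNPs array 3 those of uox (0.0572), mmp13a (0.0998) and plac8.1 (0.0798) were lost, and without SiNPs_BaP array 1 those of mmp13a (0.0623) and plac8.1 (0.0659).

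The comparison of the joint treatment with BaP addressed what the particles added to benzo[a]pyrene. Higher with both agents were timp2b (3.11 ± 0.30, adjusted p = 0.00181), cbx7a (3.02 ± 0.39, 0.00630), fosl1a (2.79 ± 0.44, 0.0176), il1b (2.73 ± 0.50, 0.0354) and mmp9 (2.65 ± 0.40, 0.0144). Lower were prph2b (-1.11 ± 0.15, 0.00935), the cone phosphodiesterase subunit pde6hb (-1.08 ± 0.14, 0.00601), rgs9a (-1.06 ± 0.14, 0.00775), kera, a corneal proteoglycan (-1.06 ± 0.07, 7.18e-04), and c1qtnf6a (-0.85 ± 0.12, 0.00994). The row of cyp1a and mpx did not differ past the test (0.09, 0.898). In all, 553 rows passed, 386 higher and 167 lower, with 233 genes that rose and 93 that fell. At the unadjusted level 7861 rows had a p under 0.05, and 23.7% of genes lay apart, against 10% by chance.

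Against BaP, 16 lists passed, 8 each way, and 5 of them with an estimated correlation. Inflammatory signalling rose (median 0.65, 17 of 37 over all rows, 27 higher and 1 lower adjusted over the list alone; 2.00e-26; 0.0158 with an estimated correlation). Hypoxia targets (0.12; 4 of 27 over all rows, 11 higher and 2 lower adjusted over the list alone; 0.0158 with an estimated correlation) and interferon genes (0.19; 2 of 21 and 4 adjusted over the list alone; 0.0216) rose as well. So did the lists of p53 (0.18; 1 of 26 and 10 adjusted over the list alone; 0.0495) and heat shock (0.12; 4 of 35 and 6 adjusted over the list alone; 0.0495). Photoreceptor genes fell (-0.34; 9 of 39 lower and 1 higher over all rows; adjusted p = 0.148 with an estimated correlation). The count of rows was 144 without BaP array 2, 167 without BaP array 3, 220 without SiNPs_BaP array 2, 234 without SiNPs_BaP array 1 and 320 without SiNPs_BaP array 3. Of the 10 named genes timp2b, cbx7a, prph2b, pde6hb and kera passed without each array in turn. The calls of rgs9a (0.0518) and c1qtnf6a (0.0601) were lost without BaP array 2. The genes fosl1a, il1b and mmp9 lost theirs without BaP array 2 (0.0729 to 0.155), BaP array 3 (0.0786 to 0.152), SiNPs_BaP array 2 (0.0659 to 0.108) or SiNPs_BaP array 3 (0.0582 to 0.116), and fosl1a (0.0718) and il1b (0.0868) also without SiNPs_BaP array 1.

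The interaction asked whether the joint treatment departed from the sum of the single treatments on the log2 scale. If the controls were not injected, an injection effect common to the 3 treated groups would enter the interaction with its sign reversed. Such an effect cannot be told apart here from a departure between the agents. In limma 0 rows passed, against 4638 at an unadjusted p under 0.05, and in simulated data the test recovered 2.99% of changed rows at a log2 difference of 0.5, 43.3% at 1 and 89.4% at 2. Among the genes of smallest p, none past the test, were nop2, a nucleolar methyltransferase (0.76 ± 0.11), moxd1 (1.15 ± 0.17), alas2 (1.00 ± 0.16) and kera (-0.80 ± 0.10), each with an adjusted p of 0.282. The mean of alas2 was 6.41 in controls, 5.12 with SiNPs, 5.81 with BaP and 5.52 with the joint treatment, and that of kera 8.69, 8.43, 8.65 and 7.59. In a fit of 1 row per named gene alone, 3 genes passed, nop2 and moxd1 (0.0442 each) and kera (0.0296), and 0 passed when the p of the fit of all rows were adjusted over the same rows. The interaction of il1b was 1.06 ± 0.71 (0.867) and that of mmp9 1.301 ± 0.570 (0.802). Of the 30 lists, 10 passed with the preset correlation and 0 with an estimated correlation.

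Some genes were followed in every comparison. Neither cyp1b1, a further AHR target, nor ahrra, the AHR repressor, passed in any contrast against control. The difference of cyp1b1 was -0.22 with SiNPs (adjusted p = 0.745), 0.14 with BaP (0.886) and 0.28 with the joint treatment (0.391), and that of ahrra -0.01, -0.05 and 0.10 (0.806 for the last). The heme oxygenase gene hmox1a stood at -0.05, 0.09 (0.947) and 0.64 (0.0550), the prothrombin gene f2 at -0.09, -0.50 (0.407) and -0.55 (0.0616), and the cardiac stress peptide gene nppa at 0.09, 0.19 and 0.17 (0.697).

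The log2 differences were compared across the 19298 genes, which are not independent replicates. The differences from control correlated at r = 0.637 between SiNPs and BaP, against 0.499 in simulated unchanged groups that shared the 3 controls; the covariance was 0.0164, against 0.0070 simulated, a difference of 0.0093. For SiNPs and the joint treatment r was 0.703 (simulated 0.499; covariance 0.0323 against 0.0071, difference 0.0253) and for BaP and the joint treatment 0.678 (simulated 0.501; 0.0297 against 0.0071, difference 0.0226). Comparisons with no array in common gave r = 0.466 for SiNPs against control and the joint treatment against BaP (rho 0.340, simulated r 0.002), and r = 0.422 for BaP against control and the joint treatment against SiNPs (rho 0.310, simulated r 0.003). Of the genes called with SiNPs, 15 of 15 that rose and 6 of 7 that fell passed in the same direction in the joint treatment. Independent lists would give 0.499 and 0.288, but the comparisons share the controls. In 20 draws of simulated unchanged groups with shared controls, as many genes ranked first by p shared 9.35 on average (at most 14) and 4.25 (at most 6). Of those that fell with BaP, 5 of 5 did, against 0.205 for independent lists and 3.55 simulated (at most 5), so the shared controls alone reached the overlaps of falling genes.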

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

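The lists named in this part stood out because they passed the test of the interaction (camera with the preset correlation). It asks whether the joint treatment departed from the sum of the single treatments. If the controls were not injected, an injection effect common to the treated groups would enter these values with its sign reversed. The values cannot tell such an effect from a departure between the agents. The lists were fixed before the data were examined, and the counts over other splits of the arrays were chosen before the results were seen.

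In 6 lists the joint treatment lay above the sum of the single treatments. The median interaction was 0.231 for inflammatory signalling (adjusted p = 1.26e-05, and 0.275 with an estimated correlation), 0.123 for hypoxia targets (0.00574 and 0.0990) and 0.113 for interferon response (0.0474 and 0.233). It was 0.108 for lysosome and endosome genes (0.0183 and 0.621), 0.101 for erythroid and globin genes (3.94e-05 and 0.0990), and 0.092 for the heat shock and unfolded protein response (8.93e-04 and 0.275).

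In 4 lists the joint treatment lay below that sum. The median was -0.146 for complement and acute phase genes (adjusted p = 0.00272, and 0.592 with an estimated correlation), -0.144 for epidermis and ionocytes (0.00187 and 0.592), -0.134 for cell cycle genes (4.38e-06 and 0.0990) and -0.082 for extracellular matrix (0.0403 and 0.678). None of the 10 passed with an estimated correlation, and 3 passed with fry, erythroid (0.0226), cell cycle (0.0230) and hypoxia (0.0230). Without 1 array at a time, interferon (adjusted p = 0.0591 to 0.178) and extracellular matrix (0.0554 to 0.178) each lost the call in 8 of 12 fits with the preset correlation. Lysosome lost it without control array 1 (0.181), SiNPs array 2 (0.0554) or BaP array 3 (0.0521), and complement (0.0747) and epidermis (0.0620) without control array 2. In 100 regroupings of the 12 arrays, the real one included, 37 gave as many lists for the interaction (highest other 20), so chance is not excluded for the 10 lists as a count.

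The 10 splits of 6 arrays are too few for a share under 0.05 in any comparison of 2 groups. The real split called 43 rows for SiNPs against control (highest other 0), 14 for BaP (0), 2744 for the joint treatment (2), 470 for the joint treatment against SiNPs (0) and 553 against BaP (0), so that in each of these 5 comparisons 1 of 10 splits, the real one, gave as many. For the lists the real split gave 13 for SiNPs, where 2 of 10 splits gave as many (highest other 18), and 14 for BaP (13), 20 for the joint treatment (16), 20 against SiNPs (11) and 16 against BaP (9), where 1 of 10 did. The test of any difference among the 4 groups called 1220 rows, as many as in 1 of 100 regroupings, the real one (highest other 208). That share is under 0.05, so chance is an unlikely source of that count. For the interaction, with 0 rows called by limma and 4638 at an unadjusted p under 0.05, 100 of 100 regroupings necessarily gave as many, up to 7.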

How the results depend on the processing

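Counting identical rows once, and adjusting the p of the fit of all rows over 1 row per named gene, were chosen after seeing the data; the other settings were not. No named gene that passed the test in either fit reversed its direction. Among values of named genes under other settings, 4694 kept their direction and side of the threshold, 352 lost the call, 72 gained it and 21 without a call changed direction. The 4694 include genes without a call, which could not lose it. Of the values with a call, 76 lost it and 68 kept it with only the arrays of the groups compared. With the block 26 lost it and 118 kept it, and with the trend and robust prior 0 lost it and 144 kept it. Among values of lists, with direction taken as the sign of the median, 1498 kept both, 142 lost the call and 44 gained it. The median changed sign in 112 without a call and in 4 with a call in either fit. The count for the joint treatment against control was 3699 with a variance prior with trend, 2887 with 1 row per named gene and 2189 with the block, against 2744. Median centring gave 1244 higher and 1482 lower rows there, and 1 row per named gene 1225 and 1662, against 1408 and 1336.

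A variance prior with trend and robust estimation called 106 rows for SiNPs, 44 for BaP, 932 against SiNPs, 861 against BaP, 1 for the interaction (kera) and 2016 for any difference. With 1 row per named gene, which tests fewer rows and refits the variance prior, the counts were 126 for SiNPs (62 higher, 64 lower, against 26 and 17), 88 for BaP (19 and 69, against 6 and 8), 841, 851 and 3 for the interaction (nop2, moxd1 and kera). With the p of the fit of all rows adjusted over the same rows they were 36, 5, 528, 544 and 0, with 2265 for the joint treatment. The prior SD was 0.136 with 2.92 degrees of freedom over all rows, and 0.115 with 4.79 in the refit. Array weights gave 308 against SiNPs. Only the arrays of the groups compared, which leaves 4 residual degrees of freedom, gave 7, 1, 865 for the joint treatment, 10 against SiNPs and 1 against BaP (cxcl18b). A fold of at least 1.5 added to the threshold left 1258 for the joint treatment, 306 against SiNPs and 363 against BaP. For trend and array weights the cause was not tested. Counting identical rows once gave 54, 15, 3158, 633, 661, 0 and 1469 rows for the 7 tests, and leaving out the lowest 25% of rows 51, 15, 3284, 632, 642, 0 and 1414. In limma 4638 rows had an unadjusted p under 0.05 for the interaction.

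With the replicate block the counts were 18 for SiNPs, 3 for BaP, 216 against SiNPs, 317 against BaP and 735 for any difference. Arrays of the same number did not vary together: over 18 pairs r ran from -0.047 to 0.061, none over 0.1, against -0.084 to 0.103 for other pairs, and 4 of 12 arrays correlated best with their own number.

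With a correlation estimated from the residuals, the lists past the threshold were 2 of 13 for SiNPs, 2 of 14 for BaP, 7 of 20 for the joint treatment, 3 of 20 against SiNPs, 5 of 16 against BaP and 0 of 10 for the interaction where the estimate replaced the preset 0.01.

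Leaving out 1 array, which lowers the number of samples, gave 4 to 32 rows for SiNPs (4 without control array 2, 5 without control array 3 or SiNPs array 3), 1 to 2 for BaP, 1561 to 2054 for the joint treatment, 66 to 164 against SiNPs, 144 to 418 against BaP and 460 to 941 for any difference. The interaction stayed at 0. The hypoxia list with SiNPs had a median of -0.001, and 0.008 to 0.03 without 1 array: it turned positive and passed at 0.03 without control array 2 (adjusted p = 0.0445) or SiNPs array 1 (0.0294) and at 0.021 without control array 3 (0.0448). The coagulation list with SiNPs, at 0.018, ran from -0.034 to 0.089, and at -0.002 without control array 3 it passed (0.0448). In both lists members lay on each side of 0, and the turn was in the sign of the median alone. With all arrays camera gave both lists the direction up, with means of 0.096 for hypoxia and 0.093 for coagulation. Why the medians crossed 0 was not tested further. As the mean of all rows of the gene, nfkbiaa (0.308, adjusted p = 0.361) and sqstm1 (0.459, 0.107) lost their call with SiNPs.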

Other observations

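The tests of explanations in this part, 4 in number, were chosen only after the results were seen, and so were the genes and rows of the next 2 paragraphs.

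The circadian clock list did not pass with the joint treatment (median -0.059, adjusted p = 0.278). Over all rows 5 of its 36 members fell and 2 rose, and 11 fell and 6 rose adjusted over the list alone. The repressor gene nr1d1 fell (-1.11, adjusted p = 0.00463), as did dbpb (-0.62, 0.0130), dbpa (-0.44, 0.0214) and hlfa (-0.59, 0.00128), a family of activators, while nfil3, a repressor that binds the same sites as that family, rose (0.86, 0.00335). In the glucocorticoid list 5 of 20 members rose and 2 fell over all rows. The kinase genes sgk1 (0.64, 0.00790) and sgk2b (0.89, 0.00210) rose, whereas klf9 (-0.82, 0.00157) and fkbp5 (-0.54, 0.0390) fell. Among epidermal genes the adhesion gene cdh1 (0.82, 0.00164) and the keratin genes krt18a.1 (0.86, 0.00243) and krt97 (0.86, 0.00748) rose, and krt5 (-0.54, 0.00263) and krt1-19e (-0.51, 0.00129) fell.

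Several rows that list more than 1 symbol passed with the joint treatment and cannot be assigned to 1 gene. Of 3 rows that list heat shock genes of the hsp70 family, 2 list hsp70l and hsp70.3, and they were 4.55 ± 0.81 (SE, n = 3 per group; adjusted p = 0.0113) and 1.504 ± 0.291 (0.0168) higher. A row that also lists hsp70.1 and hsp70.2 was 2.13 ± 0.34 higher (0.00614). The first had group means of 4.64 in controls, 6.14 with SiNPs, 6.59 with BaP and 9.19 with the joint treatment and SDs of 1.65 with SiNPs and 1.6 with BaP. The row of fabp10a, a liver fatty acid-binding protein, and api5 was lower with BaP (-1.03, 0.0449) and with the joint treatment (-1.66, 9.20e-05).

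Inflammatory signalling was higher with SiNPs than in controls, and a candidate explanation is the injection itself, since whether the controls were injected is not given in the sources used here. Per the labels' protocols all 3 treated groups were injected, so injection alone would leave them alike. The SiNPs group lay above the BaP group by a median of 0.239, higher in 31 of 37 members. The p of camera with an estimated correlation was 0.0207, not adjusted over the 30 lists. That difference is not what injection alone would give. However, the list was picked after its rise over control was seen in the same SiNPs arrays, which favours a high value. An injection response lowered in the BaP group would give the same difference. The contrast therefore cannot decide whether injection was the whole cause with SiNPs. In that contrast, run for this purpose alone, 6 rows were called and 4501 had an unadjusted p under 0.05. The erythroid and globin list had medians of -0.305 with SiNPs, -0.252 with BaP and -0.329 with the joint treatment. The joint treatment differed from SiNPs there by 0.022 (adjusted p of camera 0.375, and 0.535 with an estimated correlation). From BaP it differed by -0.068 (0.0339 and 0.22). For that list, injection alone is not set apart from the treatments. How much of each treated group's difference from control comes from the injection stays open. An effect of the particles and BaP stays a hypothesis.

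Photoreceptor genes were lower in each treated group with the preset correlation. With an estimated correlation the call was lost with SiNPs (adjusted p = 0.0954) and BaP (0.0613) and held with the joint treatment (0.0493). Scaling between arrays might lower tissue genes alike. Of 14 tissue lists in the joint treatment 10 were lower and 4 higher. Of the 4, only endothelial markers passed fry, at a median of 0.157 (adjusted p = 0.00360 with fry, and 0.141 with camera and an estimated correlation). The median difference from control over all rows was 0.00583, against -0.70 for photoreceptor genes, but RMA had set the arrays to a common distribution. With each array centred on its median 20 lists passed, as many as without. Centring moves all genes of an array alike, and camera compares a list with the other genes. Neither value could therefore have pointed to scaling. The rise of endothelial markers is not what a common lowering would give. It did not hold with camera and an estimated correlation, so scaling is not excluded. Slower development of treated embryos could also lower genes of a tissue that matures at this stage. Cell cycle genes, which fade as tissues mature, had a median of -0.216 in the joint treatment, the opposite of what slower development alone would give, but the adjusted p was 0.0733 with an estimated correlation. Slower development therefore stays open, as no series of stages was analysed here, beside a direct effect of the treatments on the retina, which was not tested.

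The row that lists cyp1a and mpx rose 3.51 with BaP, and the neutrophil transcript mpx might be what it measured. The row of mpx alone had a 95% interval that ended at 0.390 on the log2 scale for BaP against control, far below that rise, which argues against mpx as the source. An induction of cyp1a by BaP stays a hypothesis, since no row carried cyp1a alone. The arrays leave open other transcripts matched by the same probes. The AHR list did not pass with BaP by camera and the preset correlation (adjusted p = 0.0530), though it passed with fry (0.037). The 13 members tested in that list did not include cyp1a.

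The differences of SiNPs and BaP from control had a covariance 0.0093 above that simulated for shared controls. With the controls split 1 against 2, chosen after seeing the data, the comparisons shared no array, and over the 6 ways the covariance was 0.0070 to 0.0107 and r 0.202 to 0.319. The 3 controls do not make parts of 2 arrays each, so the overlaps of called genes were not counted again with split controls, and part of their excess over the simulated values may come from the shared controls, whose arrays, when 1 was left out, gave 4 to 32 rows for SiNPs. Anything that set all 3 controls apart from all treated embryos would stay in these values.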
